A study of Mus musculus with 38 samples.

How the data were processed

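Per the labels, total RNA was extracted with Trizol from snap-frozen mouse back skin treated topically with 4-hydroxytamoxifen every other day, and from sorted reporter-positive cells. Libraries were made with a TruSeq Stranded Total RNA Gold kit (knockout mice and their controls) or a stranded total RNA kit with Ribo-Zero Plus (P95H mice and their controls). The libraries are labelled as biological replicates. The whole-skin controls of both sets are labelled Cre negative, and tamoxifen was given to controls as well. In the knockout set the mice carry different numbers of tdTomato reporter alleles, and the 3 controls were treated for 12, 12 and 10 days. The Cre status of the sorted control mice is not given in the sources used here. The submitters name STAR, featureCounts and DESeq2; versions, roles and the genome build are not given in the sources used here.

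The deposited signal in each of the 4 tables is, per its name, a normalised count per gene, scaled by the authors with 1 factor per library. Each table listed 49585 genes, 93 of them with a repeated symbol, which were kept apart by identifier. In both sorted tables each value was a whole multiple of the library's smallest positive value (100% of values, tolerance 0.0001), and these multiples were taken as reads. In both whole-skin tables the values were whole multiples of 1 step per library as well, but undetected genes sat at 1 step, with 0 to 40 genes per library below it, and the multiples already had like medians in all libraries (median gene shift -0.024 to 0.022 log2 in the knockout set, -0.011 to 0.0089 in the P95H set). The deposited values carried a further division that moved the median gene by -0.26 to 0.52 and -0.99 to 1.23. In the P95H library at 28 days with replicate number 1 the low multiples clustered at a spacing of 2.35 steps, so the steps there are rescaled reads, not reads. Steps were therefore analysed for whole skin and deposited values for sorted cells. For whole skin this departed from the plan, which named the normalised counts. The change was decided from the values of the tables, before any test between groups, and the deposited values were kept as an alternative. Depth in whole skin is an estimate from steps and the further factor. It sets counting precision. With 2 to 5 animals per group the spread between animals is a limit as well, and the sizes of these limits were not compared.

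Genes with a mean of at least 10 over the libraries of a table were tested: 19450 and 18311 in the whole-skin knockout and P95H sets, 17744 in sorted knockout cells and 14914 after DMBA/TPA. limma 3.58.1 with a mean-variance trend was fitted to log2(value + 1), 1 fit per table with a coefficient per group, and its two-sided moderated tests were adjusted over all genes tested by the Benjamini-Hochberg method, with a threshold of 0.05. Of a difference of effects (P95H at 28 minus 12 days) the interaction itself was tested. 40 lists of pathway genes and cell type markers, written before the data were examined, were tested by camera with a preset correlation of 0.01 where at least 5 members were measured, adjusted over the lists of a comparison; counts adjusted over the list alone use the members' limma p values. Camera with an estimated correlation and fry were run beside it. Lists described in the report, genes shared between further pairs of comparisons, and the fit without sorted knockout replicate 2 with its named genes were chosen after the data were examined. R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, data.table (version 1.17.8), python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.

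Named genes were chosen by a rule written before the data were examined. In each comparison it takes Srsf2, the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 50, no overlap between groups and a symbol that is not a predicted or RIKEN model. It adds up to 4 members of each described list with the smallest p, and always Trp53, Cdkn1a, Mdm2, Mki67, Ccnb1, Krt14, Krt5, Krt10, Krt1, Krt6a, Krt16 and Krt17. Genes named outside the rule (4930428N03Rik, 4931403M11Rik and Gm43430, and Dnah17 where it is not among the largest) were chosen after their values were seen. Positions are from GENCODE M21 (GRCm38): 43749 of the 49585 identifiers matched it with their version, 49326 without, and 47169 symbols were equal. 4931403M11Rik has no position there.

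The test was checked on simulated data: 200 genes were changed, 100 by 2-fold and 100 by 4-fold, in values drawn at the spread of each comparison. limma recovered 58% and 89% of them (2-fold and 4-fold) at 10 days in whole skin, 75% and 97% in P95H skin at 28 days, 3% and 47% in sorted knockout cells and 73% and 94% in sorted cells after DMBA/TPA, with at most 13 unchanged genes called. No library was a copy of another of its group (lowest chi-square per degree of freedom 6.97), and libraries of different groups were not compared in this way. Alternatives, 1 at a time, were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, equal totals, TMM, array weights, the replicate number as a block, tdTomato alleles as a covariate, only the groups compared, only the 12-day controls, pooled controls, each library left out, and edgeR and DESeq2 on the reads of sorted cells. The deposited values of whole skin, which the plan had named, became an alternative after the data were seen. All tables and columns of values were used.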

Results

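RNA was sequenced from the back skin of mice in which Srsf2, which encodes an SR protein that binds pre-mRNA during splicing, was either deleted or carried the P95H mutation. Tamoxifen was applied to the skin, and Krt14-CreER, a recombinase active in cells that express keratin 14, acted on the allele. The comparisons ask which transcripts differ from control skin once SRSF2 is lost or mutated. The knockout set of whole skin held 3 Cre-negative controls, treated for 10 or 12 days, and 3 knockout mice each at 4, 10 and 12 days. The P95H set held 5 controls and 2 P95H mice at 12 days, and 3 controls and 4 P95H mice at 28 days. Reporter-positive cells were sorted from 3 control and 3 knockout mice at 10 days. The same kind of cells came from 3 control and 3 heterozygous P95H mice after tamoxifen injection and 20 weeks of DMBA/TPA, a mutagen and a tumour promoter used to induce skin tumours. Each of the 38 libraries came from 1 animal. Estimated depth was 24.9 to 36.8 M reads (M for mega) in the knockout set and 7.37 to 32.2 M reads in the P95H set. The sorted libraries held 45.9 to 92.8 M reads in the knockout experiment and 10.98 to 17.2 M reads after DMBA/TPA. Levels below are group means ± SD, as steps (the unit of which every value of a whole-skin library is a whole multiple) in whole skin and as normalised counts in sorted cells. Folds were taken on the log2(value + 1) scale, and adjusted p values of genes came from limma.

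Srsf2 (ENSMUSG00000034120.18; chromosome 11, 116849901 to 116853094, GRCm38 annotation) was measured in every sample. In the knockout set of whole skin its level was 2920 ± 65.9 steps in controls (n = 3), 2637 ± 173 at 4 days, 3256 ± 376 at 10 days and 2415 ± 131 at 12 days (n = 3 each). None of the 3 differences passed limma (log2 -0.15, adjusted p = 0.369; 0.15, adjusted p = 0.286; -0.28, adjusted p = 0.164). With every library rescaled to the same total, the 10-day difference had the opposite sign (-0.17). In P95H skin the Srsf2 transcript stood at 3602 ± 22.6 steps against 3460.2 ± 429 in controls at 12 days, and at 3200.5 ± 404 against 3165 ± 157 at 28 days. Neither difference passed (adjusted p = 0.802 and 0.974). In sorted knockout cells Srsf2 fell 6.55-fold, from 18782 ± 1602 to 2973 ± 941 normalised counts (log2 -2.71, SE 0.27, n = 3 each, adjusted p = 0.043 by limma). In sorted heterozygous P95H cells it was 4126 ± 331 against 4375 ± 312 (n = 3 each, adjusted p = 0.697 by limma).

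**Figure D1:**
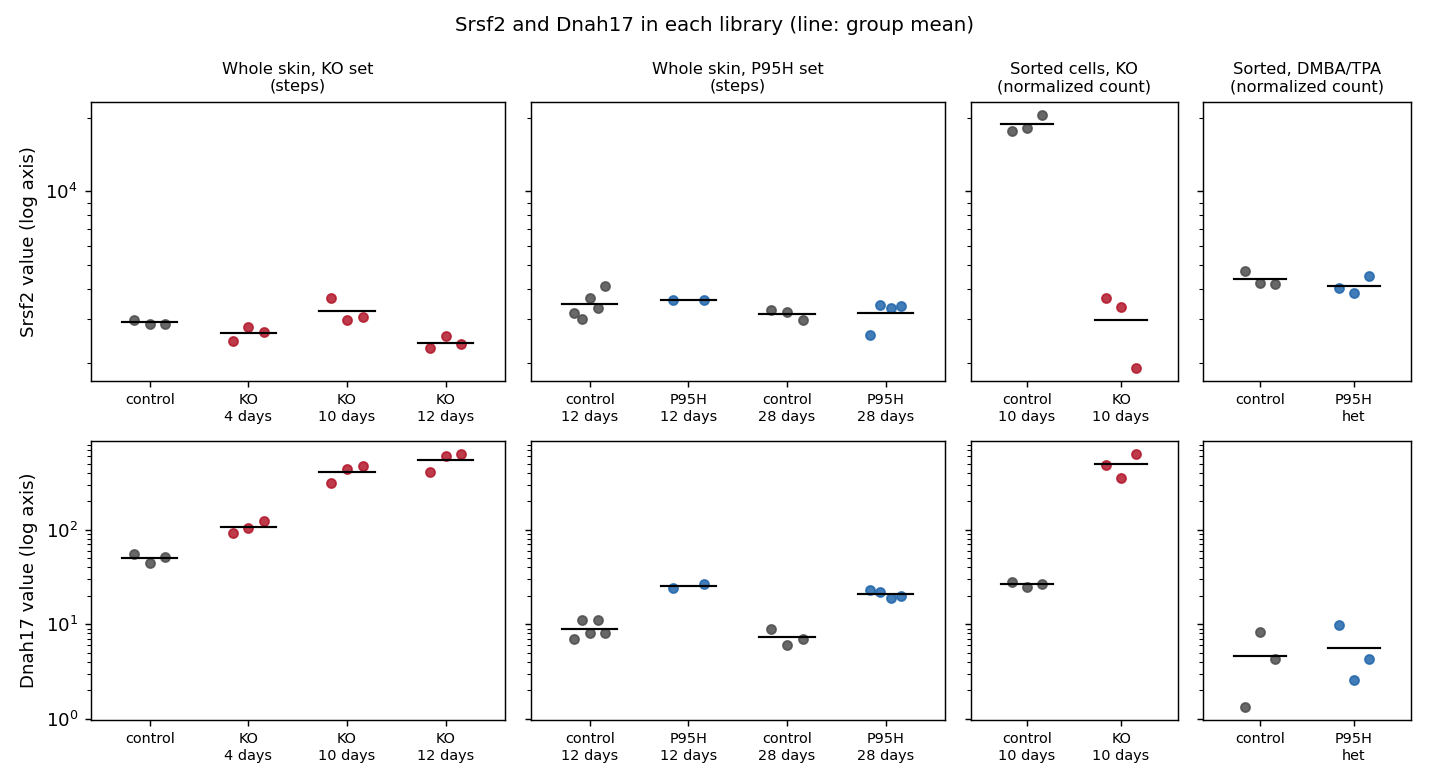
Level of Srsf2 (top) and Dnah17 (bottom) in each library, on log axes, in steps for whole skin and in normalised counts for sorted cells; points are libraries and lines are group means. In sorted cells all 3 knockout libraries lay below all 3 controls for Srsf2 and above them for Dnah17.

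At 4 days of deletion, macrophage, fibroblast and mitosis genes were among the raised groups in whole skin. The controls were treated for 10 or 12 days, so every comparison at 4 days mixes the deletion with a shorter treatment. Of the 24 measured macrophage and dendritic cell markers, 15 rose and 1 fell (16 and 1 adjusted over the list alone). The monocyte chemokine receptor Ccr2 (4.14-fold, adjusted p = 0.00403), the mannose receptor Mrc1 (3.20-fold, adjusted p = 0.00656) and lysozyme Lyz2 (3.48-fold, adjusted p = 0.00671) were among those that rose. Fibroblast markers rose in 17 of 23 cases (19 adjusted over the list alone) and none fell, with collagen Col5a1 (2.95-fold, adjusted p = 0.00791), fibrillin Fbn1 (2.80-fold, adjusted p = 0.00859) and the growth factor receptor Pdgfra (2.07-fold, adjusted p = 0.00671) as examples. Both lists passed camera (adjusted p = 1.12e-08 and 1.74e-10; adjusted p = 0.595 for each with an estimated correlation). Of 59 mitosis genes 17 rose and none fell (52 adjusted over the list alone), among them the kinetochore gene Ndc80 (2.31-fold, adjusted p = 0.0206) and the kinesin Kif23 (2.21-fold, adjusted p = 0.0227). Camera gave adjusted p = 7.86e-16 for mitosis (adjusted p = 0.595 with an estimated correlation). Interferon response genes rose in 8 of 34 cases (18 adjusted over the list alone), including Mx1 (2.29-fold), Oasl1 (3.44-fold) and Oas1a (3.03-fold), and replication-dependent histones in 4 of 60 (3 adjusted over the list alone), including Hist1h4c (2.02-fold) and Hist1h2bn (3.06-fold). These lists had adjusted p = 3.13e-10 and 6.99e-08 by camera (adjusted p = 0.595 and 0.712 with an estimated correlation).

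Some genes of the hair follicle and the cornified layer fell at 4 days. Among 42 hair shaft and inner root sheath genes 4 fell (3 adjusted over the list alone): the hair regulators Foxn1 (3.42-fold, adjusted p = 0.0184) and Gata3 (1.79-fold, adjusted p = 0.0451) and the keratins Krt84 (18.4-fold, adjusted p = 0.0323) and Krt32 (5.003-fold, adjusted p = 0.0351). The median log2 change of that list was -3.22 (camera adjusted p = 1.01e-07; adjusted p = 0.712 with an estimated correlation). Its score (mean log2 value) ran from 6.37 to 11.2 among the 3 controls, a range of 4.81. Of 23 hair follicle stem cell markers 6 fell and 1 rose (11 and 2 adjusted over the list alone). The stem cell transcription factor Sox9 (2.16-fold, adjusted p = 0.00724), Foxc1 (1.62-fold) and Barx2 (1.87-fold) fell, and Cd34 (2.21-fold), which endothelial and stromal cells also express, rose. Basal keratinocyte markers went both ways, with 2 rising and 2 falling of 23 (2 and 5 adjusted over the list alone); Trp63 (1.76-fold) and Cxcl14 (1.83-fold) fell, whereas Igfbp5 (1.47-fold) and Ifitm3 (2.10-fold) rose. In the cornified layer list 4 of 37 fell (4 adjusted over the list alone), namely Sprr4 (5.48-fold), involucrin (Ivl, 1.76-fold), Crct1 (1.68-fold) and corneodesmosin (Cdsn, 1.87-fold). These 3 lists had adjusted p = 0.00688, 0.00215 and 0.00768 by camera (adjusted p = 0.595, 0.595 and 0.712 with an estimated correlation). The cornified layer lost its call without control replicate 1 (adjusted p = 0.073) or knockout replicate 3 (adjusted p = 0.0537).

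The largest rises at 4 days were those of the histone H4 gene Hist1h4m (27.9-fold, adjusted p = 0.0374), the gasdermin Gsdmc (12.98-fold, adjusted p = 0.00742), the macrophage-secreted Cd5l (11.2-fold, adjusted p = 0.00125), the myeloid receptor Pira2 (7.71-fold), the endosomal receptor Tlr13 (6.89-fold), Klk1b1 (6.72-fold), Gapdhs (6.70-fold) and Btnl2 (6.11-fold). The low-affinity IgE receptor Fcer2a (11.9-fold, adjusted p = 0.016), Add2 (8.10-fold), Car6 (7.88-fold) and the striated muscle gene Xirp1 (6.10-fold) were among the largest falls. Trim12a lay at the floor of 1 step in all 3 knockout libraries, against 247 ± 49.2 in controls (adjusted p = 0.00725), but at 158 ± 22.5 at 10 days and 242, 190 and 4 at 12 days, so its loss did not follow the length of deletion. None of the 12 keratin, cell cycle and p53 genes always named passed; Mki67, a proliferation marker, was 9191 ± 4482 against 4484 ± 2495 (adjusted p = 0.114), and Krt17 was 15527 ± 3875 against 32267 ± 6981 (adjusted p = 0.0566). In all, 2205 of 19450 genes passed limma, 1403 higher and 802 lower (n = 3 each). Every knockout library lay on 1 side of every control for 5721 genes (29.4%; chance gives 10%). The count was 535 without control replicate 1, 1187 without knockout replicate 1, 295 without knockout replicate 3, 764 with only these 2 groups in the fit and 743 on the deposited values. Across left-out libraries, 22 of the 52 passing genes taken by the naming rule kept the call whichever library was left out. With every library rescaled to the same total, 1060 higher and 1035 lower were called.

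At 10 days of deletion, genes of the growing hair were widely raised against control skin. Of 42 measured hair shaft and inner root sheath genes 38 rose and none fell (41 adjusted over the list alone), with a median log2 change of 6.31. The regulators Foxn1 (4.44-fold, adjusted p = 0.00633), Dlx3 (7.96-fold, adjusted p = 0.00633) and Dlx4 (17.5-fold, adjusted p = 0.00643) rose with the hair keratin Krt32 (12.8-fold, adjusted p = 0.00491). The largest rises in the tissue were those of hair keratin-associated proteins, follicle keratins and Gprc5d. Krtap5-2 went from 28 ± 38.1 to 7419.7 ± 4187 steps (430.4-fold, adjusted p = 0.0043), and Krtap5-3 (226-fold), Krtap15 (189.5-fold), Krtap19-3 (165-fold), Gprc5d (162-fold), Krt82 (155-fold), Krt71 (147-fold) and Krt25 (142-fold) followed. Pigment cell genes moved with them: all 11 melanocyte markers rose (11 adjusted over the list alone), among them tyrosinase (Tyr, 22.7-fold), Tyrp1 (14.7-fold) and Dct (6.92-fold). Both lists passed camera (adjusted p = 1.57e-13 and 5.64e-08; adjusted p = 0.518 for each with an estimated correlation). The hair list score (mean log2 value) ran from 6.37 to 11.2 among the 3 controls.

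Proliferation genes rose together in whole skin at 10 days. The same 3 libraries had hair list scores of 14.8 to 15.3, so hair cycle stage and deletion cannot be told apart for lists of this day. In sorted knockout cells the medians (log2) were 0.11 for mitosis, 0.61 for DNA replication, 0.052 for homologous recombination and Fanconi and 0.15 for histones. Camera gave adjusted p = 0.137, 1.54e-06, 0.42 and 0.138 for them there. Mitosis genes rose in 41 of 59 cases (54 adjusted over the list alone), DNA replication genes in 35 of 43 (40 adjusted over the list alone) and homologous recombination and Fanconi genes in 16 of 42 (17 adjusted over the list alone), and none fell in these 3 lists. The checkpoint gene Bub1 (2.70-fold, adjusted p = 0.0151), the origin recognition gene Orc1 (3.71-fold, adjusted p = 0.00271), the helicase subunit Mcm7 (1.87-fold, adjusted p = 0.00763) and the repair gene Brca1 (3.24-fold, adjusted p = 0.00826) were examples. Of 60 replication-dependent histones 46 rose and 1 fell (51 and 1 adjusted over the list alone); Hist2h2ac (2.19-fold) and Hist1h3g (3.53-fold) rose, and Hist1h2al fell to 1.33 ± 0.577, near the floor, from 44.7 ± 19.01. Hist1h2al was 19, 63 and 75 at 4 days and 19, 2621 and 57 at 12 days. The 4 lists had adjusted p = 1.57e-13, 1.59e-13, 1.16e-05 and 2.52e-13 by camera (adjusted p = 0.52, 0.518, 0.52 and 0.518 with an estimated correlation). Mki67 rose 2.57-fold (adjusted p = 0.0291) and cyclin B1, Ccnb1, 2.40-fold (adjusted p = 0.0226).

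Wound and stress keratinocyte genes rose in 27 of 36 cases and 1 fell (31 and 1 adjusted over the list alone; camera adjusted p = 4.26e-11, and adjusted p = 0.518 with an estimated correlation). The growth factor Tgfa (2.65-fold, adjusted p = 0.00477), Sprr1a (5.71-fold, adjusted p = 0.00658), Sprr2a3 (14.9-fold) and the wound keratins Krt17 (3.38-fold), Krt16 (7.91-fold) and Krt6a (5.98-fold) rose, whereas the differentiation keratins Krt10 (2.11-fold) and Krt1 (1.74-fold) fell. Of 42 p53 targets 15 rose and 5 fell (15 and 7 adjusted over the list alone). Among them Zfp365 (3.15-fold, adjusted p = 0.00319), Plk3 (2.90-fold, adjusted p = 0.0043), Tnfrsf10b (2.05-fold) and Btg2 (1.61-fold) rose. So did the cell cycle inhibitor Cdkn1a (5486 ± 599.9 against 2920 ± 576, adjusted p = 0.0115) and Trp53 itself (1.38-fold, adjusted p = 0.0478). Mdm2, a p53 target that limits p53, was 1432 ± 19.1 against 1269 ± 149 (adjusted p = 0.217). The p53 list had adjusted p = 0.0188 by camera (adjusted p = 0.518 with an estimated correlation, and 0.0594 on the deposited values), and its median log2 change of 0.21 became -0.11 at equal totals. In sorted knockout cells of the same day its median was -0.12 (camera adjusted p = 0.912), with 4 rising and 6 falling adjusted over the list alone. There Cdkn1a, Mdm2 and Trp53 stood at log2 -0.69, -1.32 and -0.22 (limma adjusted p = 0.233, 0.112 and 0.641).

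Genes of RNA processing and translation were higher in whole skin at 10 days. In sorted knockout cells of the same day the list medians (log2) were 0.20 for core spliceosome, -0.44 for SR proteins and -0.23 for cytosolic ribosomal proteins. Camera gave adjusted p = 0.172, 0.137 and 0.0363 for them there, and fry gave adjusted p = 0.0133 for SR proteins. Core spliceosome genes rose in 16 of 34 cases (19 adjusted over the list alone), as in Snrpd2 (1.82-fold, adjusted p = 0.00713) and Snrnp40 (1.63-fold), and none fell (camera adjusted p = 9.30e-06; adjusted p = 0.518 with an estimated correlation). Among 12 SR proteins, the family of SRSF2, 6 rose and none fell (8 adjusted over the list alone), including Srsf7 (1.45-fold), Srsf1 (1.35-fold) and Srsf6 (1.22-fold). That list had adjusted p = 0.0074 by camera (adjusted p = 0.518 with an estimated correlation), and at equal totals its median of 0.31 became -0.0043 and the call was lost (adjusted p = 0.0895). Srsf6 then stood at -0.027. Cytosolic ribosomal protein genes rose in 39 of 86 cases and 1 fell (54 and 1 adjusted over the list alone), with Rpl7a (1.57-fold) and Rps13 (1.501-fold) as examples (camera adjusted p = 1.48e-11; adjusted p = 0.518 with an estimated correlation).

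Skeletal muscle, endothelial and adipocyte markers, and mitochondrially encoded genes, were lower at 10 days. Skeletal muscle genes fell in 18 of 20 cases (19 adjusted over the list alone), as in myosin Myh1 (2.78-fold, adjusted p = 0.00977) and actin Acta1 (2.35-fold, adjusted p = 0.0101). Endothelial markers fell in 11 of 15 (13 adjusted over the list alone), as in Cdh5 (2.09-fold, adjusted p = 0.00217) and Kdr (2.01-fold, adjusted p = 0.00218). Adipocyte markers fell in 7 of 18 (7 adjusted over the list alone), as in Gpd1 (3.35-fold, adjusted p = 0.00033) and Adrb3 (2.73-fold, adjusted p = 0.00321). Mitochondrially encoded genes fell in 8 of 11 (9 adjusted over the list alone), as in mt-Nd4 (2.05-fold, adjusted p = 0.00325) and mt-Cytb (1.98-fold, adjusted p = 0.00664). None rose in these 4 lists, which had adjusted p = 7.37e-08, 1.84e-07, 1.60e-05 and 3.63e-05 by camera (adjusted p = 0.518 for each with an estimated correlation). The largest falls of single genes included Cyp2w1 (16.4-fold), the transglutaminase Tgm7 (14.1-fold), the cytokine receptor subunit Il20ra (12.7-fold), guanylin (Guca2a, 8.63-fold), Wnt16 (7.55-fold), Ankdd1a (5.99-fold) and the kainate receptor Grik1 (5.83-fold).

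In all, 4913 of 19450 genes passed limma at 10 days (n = 3 each), 2593 higher and 2320 lower, and of the 12 genes always named 9.0 passed. The groups did not overlap for 8382 genes (43.1%; chance gives 10%). The count was 3143 without control replicate 1, 1424 without control replicate 2, and 3214, 2309 and 3061 without knockout replicates 1, 2 and 3; 55 of the 88 passing genes taken by the naming rule kept the call in each of these fits. Equal totals moved the median of all genes to -0.34 (log2) and gave 1212 higher and 6806 lower, and the deposited values moved it to 0.26 and gave 3418 higher and 550 lower.

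At 12 days of deletion wound keratinocyte genes were higher than in control skin. Of 36 wound and stress keratinocyte genes 11 rose and none fell (19 and 1 adjusted over the list alone; camera adjusted p = 5.46e-08, and adjusted p = 0.724 with an estimated correlation). Stfa1, a stefin of the epidermis and of myeloid cells, went from 6 ± 3 to 366 ± 169.9 steps (52.3-fold, adjusted p = 0.00206), and Serpinb3a (33.9-fold, adjusted p = 0.00602), Sprr2d (65.9997-fold, adjusted p = 0.0125) and Sprr2a3 (27.3-fold, adjusted p = 0.0125) rose. The wound keratin Krt6b (437-fold, adjusted p = 0.0209), the calprotectin subunit S100a9 (25.8-fold), Gsdmc (63.3-fold) and Gapdhs (19.4-fold) were also among the largest rises. Krt16 was 16859 ± 16614 against 794 ± 432 (adjusted p = 0.0591). Of 8 neutrophil markers 1 rose, the chemokine receptor Cxcr2 (5.88-fold, adjusted p = 0.025) (5 rose adjusted over the list alone). That list had adjusted p = 0.00284 by camera, adjusted p = 0.617 with an estimated correlation and 0.0577 over genes with a mean of at least 50. Of 42 p53 targets 2 rose, the polymerase Polk (1.85-fold, adjusted p = 0.026) and the apoptosome gene Apaf1 (1.47-fold, adjusted p = 0.0414), and none fell (8 and 0 adjusted over the list alone). Camera gave adjusted p = 0.00284 for that list (adjusted p = 0.517 with an estimated correlation).

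Other groups differed as lists at 12 days with few or no genes that passed alone. No fibroblast or macrophage and dendritic cell marker passed over all genes (7 of 23 and 3 of 24 rose adjusted over the list alone, and 1 macrophage marker fell), with medians of 0.63 and 0.70. Pdgfra was 7516 ± 1236 against 4836 ± 693 and Mrc1 18883 ± 4958 against 8967 ± 1769. Among 18 adipocyte markers the glycerol channel Aqp7 (2.73-fold, adjusted p = 0.025) fell (1 adjusted over the list alone; median -0.72). No hair shaft and inner root sheath gene of 42 passed over all genes (4 fell adjusted over the list alone), and the median was -2.94. The score of the hair list ranged over 4.81 among the controls alone. These 4 lists had adjusted p = 2.31e-05, 4.10e-05, 8.78e-05 and 4.98e-09 by camera (adjusted p = 0.724 for each with an estimated correlation), and the hair list lost its call with array weights (adjusted p = 0.061). Falls of single genes included Fcer2a (19.6-fold), Guca2a (6.18-fold), the magnesium channel Trpm6 (3.34-fold), the metallothionein Mt4 (3.28-fold), Cbs (3.15-fold), Pramef12 (3.01-fold) and the protease Tmprss2 (3.01-fold). Rps15a-ps7 was at 1.33 ± 0.577, near the floor, against 155 ± 199 in controls. In all, 249 genes passed limma (n = 3 each), 160 higher and 89 lower, and none of the 12 genes always named. The groups did not overlap for 4398 of 19450 genes (22.6%; chance gives 10%). The count was 80, 79 and 44 without control replicates 1, 2 and 3 (the last the 10-day control), 75, 144 and 43 without knockout replicates 1, 2 and 3. It was 153 over genes with a mean of at least 50, 947 with array weights and 111 with only these 2 groups in the fit, and 5 of the 20 passing genes taken by the naming rule kept the call whichever library was left out. The deposited values gave 92 higher and 18 lower.

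A small group of genes was higher in knockout skin at all 3 times and in sorted knockout cells; it was picked out after its values were seen. Dnah17, which encodes an axonemal dynein heavy chain (ENSMUSG00000033987.16; chromosome 11, 118021723 to 118130634), stood at 50.7 ± 5.51 steps in controls and rose 2.08-fold at 4 days, 7.83-fold at 10 days and 10.5-fold at 12 days, to 549 ± 122 (adjusted p = 0.0123, 8.15e-05 and 2.29e-05). The long noncoding RNA 4930428N03Rik (ENSMUSG00000089887.1; chromosome 14, 24617557 to 24788520) and 4931403M11Rik (ENSMUSG00000038792.3) lay at the floor of 1 step in all 3 controls. The first reached 20.7 ± 4.73, 83 ± 10 and 111 ± 21.8 steps at 4, 10 and 12 days, and the second 26 ± 5.57, 111 ± 25.7 and 150 ± 45.5 (n = 3 each; highest adjusted p = 0.000302 by limma). In P95H skin Dnah17 rose 2.68-fold at 12 days (25.5 ± 2.12 against 9 ± 1.87) and 2.66-fold at 28 days (21 ± 1.83 against 7.33 ± 1.53; adjusted p = 0.00417 and 0.00233). In sorted cells after DMBA/TPA it was 5.58 ± 3.80 in heterozygous P95H and 4.66 ± 3.52 in control mice, under the minimum mean for a test.

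Knockout skin at 12 days was also compared directly with knockout skin at 4 days. No control treated for 4 days was used here, so these differences mix the deletion with the longer treatment. Dnah17 rose 5.03-fold between these times (adjusted p = 0.00373), with Stfa1 (21.5-fold, adjusted p = 0.0183), the chemokine Ccl20 (4.89-fold, adjusted p = 0.0234), Rrh (3.31-fold), Csta1 (2.25-fold), Tmem56 (2.18-fold), the defensin Defb1 (2.05-fold) and the cell cycle inhibitor Cdkn2b (1.77-fold). Macrophage-secreted Cd5l (9.19-fold, adjusted p = 0.00736), the collagen Col6a6 (4.61-fold), the lymphatic receptor Lyve1 (3.41-fold), the chemokine Ccl6 (2.49-fold), Ms4a8a (2.50-fold), Fcna (2.46-fold) and the protease Adamts15 (2.002-fold) fell. Among 36 wound and stress keratinocyte genes Stfa1 alone passed over all genes (23 rose adjusted over the list alone; median log2 2.08), and S100a9 was 618 ± 50.7 against 32.3 ± 22.2 (adjusted p = 0.0674). No gene of the other described lists passed over all genes. Adjusted over the list alone, 28 of 59 mitosis genes and 7 of 34 interferon response genes fell and 11 of 37 cornified layer genes rose, with medians of -0.77, -0.60 and 0.48. Espl1 was 874 ± 205 against 1756 ± 390.0, Mx1 325 ± 32.1 against 595 ± 116 and Rptn 2167 ± 1248 against 396 ± 234. The 4 lists had adjusted p = 1.55e-16, 3.14e-17, 1.31e-08 and 1.31e-08 by camera (adjusted p = 0.685 for each with an estimated correlation). In all, 28 genes passed limma (n = 3 each), 21 higher and 7 lower; 3594 of 19450 genes did not overlap (18.5%; chance gives 10%), and none of the 12 genes always named passed (smallest adjusted p = 0.163). The count was 3, 11 and 7 without 4-day replicates 1, 2 and 3, 4 and 8 without 12-day replicates 2 and 3. Of the 15 passing genes named here, 2 kept the call whichever library was left out. The count was 60 with a pseudocount of 5, 53 with no filter, 15 over genes with a mean of at least 50 and 975 with array weights. Equal totals gave 52 higher and 9 lower, and the deposited values gave 23 higher and 3 lower with the median of all genes at 0.15.

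**Figure D2:**
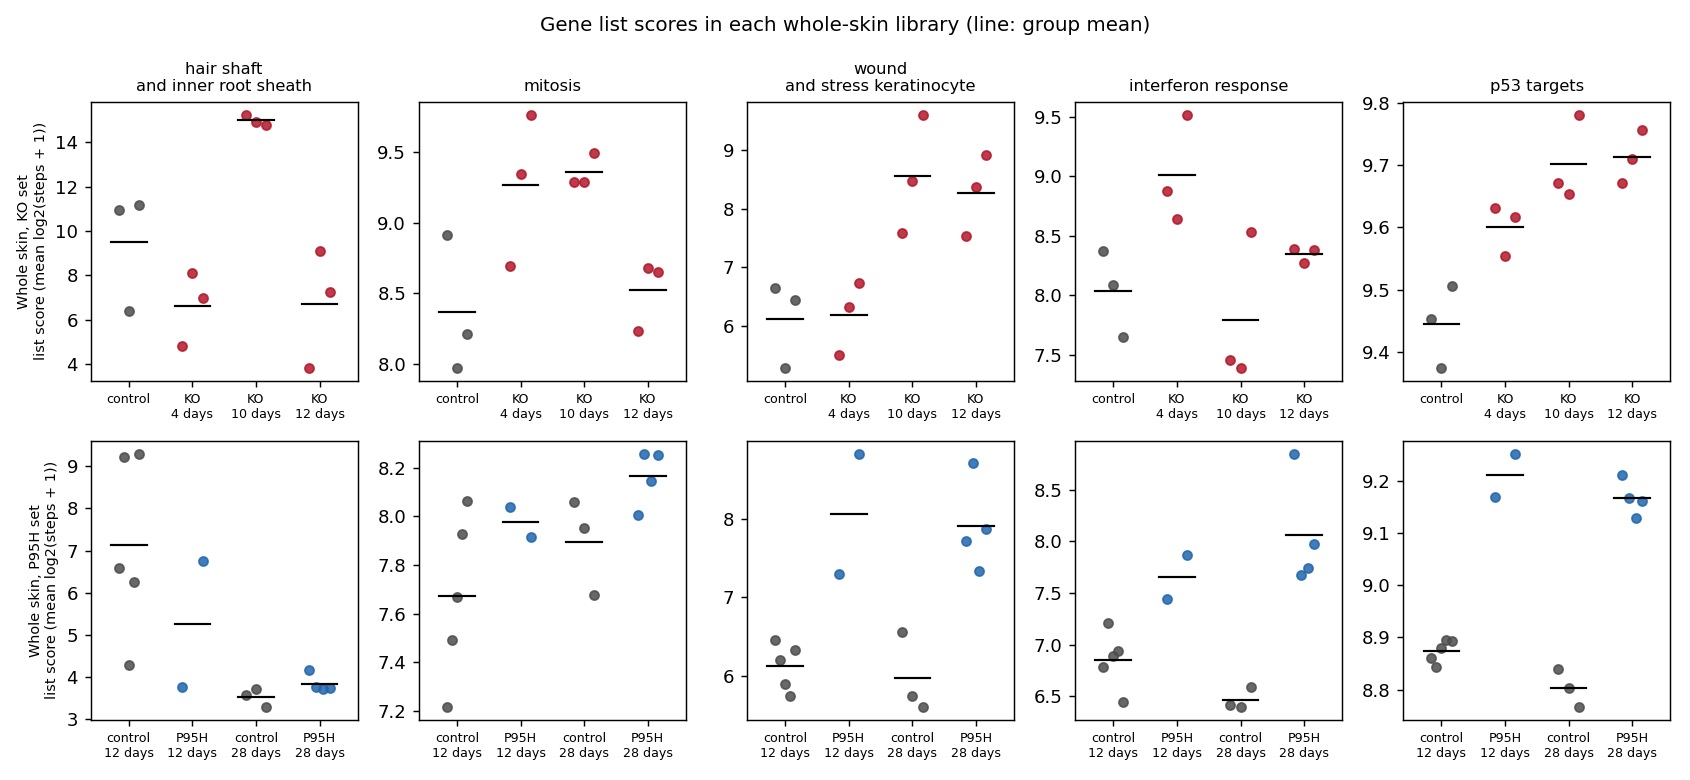
Score (mean log2(steps + 1) of the members) of 5 gene lists in each whole-skin library, knockout set above and P95H set below; points are libraries and lines are group means. The hair list was highest at 10 days of deletion and varied widely among controls, and P95H libraries lay above controls of the same day for p53 targets.

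In P95H skin at 12 days, p53 target genes, wound and stress keratinocyte genes and lipid genes were higher than in controls of the same day. Every P95H library of whole skin was Cre positive and every control Cre negative. The mutation and active Cre therefore cannot be told apart at either day for any gene or list. Of 42 p53 targets 15 rose and none fell (18 and 2 adjusted over the list alone), including Psrc1 (2.64-fold, adjusted p = 0.000328), the death receptor Tnfrsf10b (2.20-fold, adjusted p = 0.000526), Zmat3 (1.53-fold, adjusted p = 0.000593) and the pro-apoptotic Pmaip1 (2.84-fold, adjusted p = 0.000977). This was the list whose call held with an estimated correlation as well (adjusted p = 1.42e-06 by camera; adjusted p = 0.0199 with an estimated correlation). In sorted heterozygous P95H cells after DMBA/TPA the p53 list had a median of -0.07 (log2, camera adjusted p = 0.433). Cdkn1a in P95H skin at 12 days rose from 2864 ± 405 to 4510 ± 246 steps (adjusted p = 0.0089), and Mdm2 was 1458 ± 208 against 1145 ± 49.8 (adjusted p = 0.084). Of 32 wound and stress keratinocyte genes 13 rose and none fell (23 adjusted over the list alone), led by Serpinb3a (40.6-fold, adjusted p = 2.77e-05), Krt6b (39.9-fold, adjusted p = 0.00161), Stfa1 (12.4-fold) and Stfa3 (8.79-fold). Krt16, Krt14 and Krt1 also rose (11.8, 1.91 and 2.57-fold), as did Stfa2 (22.1-fold), Sprr1b (15.6-fold), Gsdmc (12.6-fold) and repetin (Rptn, 10.5-fold). These 3 keratins and Cdkn1a were the 4 of the 12 genes always named that passed, so Krt6a and Krt17 did not. In the cornified layer list 10 of 35 rose and 2 fell (17 and 2 adjusted over the list alone); filaggrin, Flg (5.72-fold, adjusted p = 0.000177), and Slurp1 (3.35-fold, adjusted p = 1.54e-05) rose and Lce1m (2.35-fold) fell. These 2 lists had adjusted p = 4.23e-13 and 9.85e-09 by camera (adjusted p = 0.289 for each with an estimated correlation).

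Lipid genes rose in 3 lists at 12 days, and none fell. Sebaceous gland genes rose in 13 of 24 cases (19 adjusted over the list alone), as in the elongase Elovl3 (3.55-fold, adjusted p = 3.57e-05) and Acox2 (3.63-fold, adjusted p = 0.00184). Cholesterol and lipid synthesis genes rose in 12 of 26 (16 rose and 1 fell adjusted over the list alone), as in Msmo1 (1.76-fold, adjusted p = 0.00127) and Cyp51 (1.51-fold, adjusted p = 0.00267). Epidermal lipid barrier genes rose in 11 of 25 (14 adjusted over the list alone), as in Fa2h (2.49-fold, adjusted p = 0.00123) and Degs2 (6.29-fold, adjusted p = 0.0016). The 3 lists had adjusted p = 8.10e-12, 6.80e-10 and 3.26e-07 by camera (adjusted p = 0.289 for each with an estimated correlation). Interferon response genes rose in 5 of 34 cases (18 adjusted over the list alone), including Isg15 (4.18-fold) and Ifit1 (3.30-fold) (camera adjusted p = 1.54e-10; adjusted p = 0.345 with an estimated correlation). Skeletal muscle genes fell in 4 of 20 (12 adjusted over the list alone), as in Mylpf (1.65-fold) and Neb (1.45-fold) (camera adjusted p = 8.29e-08; adjusted p = 0.289 with an estimated correlation). Among 42 hair shaft and inner root sheath genes Gata3 (1.68-fold, adjusted p = 0.000766) fell (1 adjusted over the list alone) with a list median of -1.93 (camera adjusted p = 2.12e-06; adjusted p = 0.662 with an estimated correlation). That call ended without P95H replicate 1 (median -0.39, adjusted p = 0.247) and with controls of both days pooled (adjusted p = 0.161).

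The largest falls of single genes at 12 days were Tgm7 (11.8-fold, adjusted p = 0.00103), Mrgprb11-ps (7.16-fold), the laminin Lama1 (5.76-fold), the potassium channel Kcnj16 (5.59-fold), Car6 (5.17-fold), Il20ra (4.88-fold), the chemokine receptor Ccr4 (4.61-fold) and Mrgprb3 (4.27-fold). In all, 1269 of 18311 genes passed limma (2 P95H against 5 control mice), 726 higher and 543 lower, and 5082 genes did not overlap between the groups (27.8%; chance gives 9.52%). The count was 779 without P95H replicate 1, 323 without P95H replicate 2 and 2329 with array weights, and 26 of the 57 passing genes taken by the naming rule kept the call whichever library was left out. The deposited values gave 94 higher and 106 lower, with the median of all genes at -0.10, and 24 of 58 values of genes named for 12 days kept sign and side of the threshold.

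In P95H skin at 28 days interferon response genes were the most widely raised group: 28 of 34 rose and none fell (32 adjusted over the list alone). The chemokine Cxcl10 went from 12 ± 1.73 to 186 ± 104 steps (13.06-fold, adjusted p = 3.56e-05), with Isg15 (20.7-fold, adjusted p = 3.56e-05), Oas1a (5.25-fold, adjusted p = 8.91e-05) and the signalling factor Irf9 (2.11-fold, adjusted p = 9.54e-05). Cornified layer genes rose in 25 of 35 cases and 1 fell (30 and 1 adjusted over the list alone), with Flg (7.89-fold, adjusted p = 2.26e-05), Slurp1 (3.02-fold, adjusted p = 9.20e-06), involucrin (Ivl, 2.24-fold) and Lce1g (5.38-fold). Of 32 wound and stress keratinocyte genes 19 rose and none fell over all genes (24 and 1 adjusted over the list alone), among them Serpinb3a (24.2-fold, adjusted p = 3.56e-05), Stfa2 (32.6-fold), Sprr2a3 (28.4-fold) and Stfa3 (7.16-fold). The 3 lists had adjusted p = 2.12e-24, 8.35e-16 and 7.55e-13 by camera (adjusted p = 0.324 for each with an estimated correlation). Keratins of the wounded epidermis rose, Krt16 (10.4-fold), Krt6b (23.2-fold), Krt6a (3.80-fold) and Krt17 (2.29-fold), as did the basal and differentiation keratins Krt14 (1.72-fold), Krt5 (1.29-fold) and Krt1 (2.05-fold).

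Of 42 p53 targets 18 rose and 2 fell at 28 days (22 and 4 adjusted over the list alone), including Psrc1 (3.03-fold, adjusted p = 5.14e-05), Zfp365 (2.45-fold, adjusted p = 0.000106), Dcxr (2.44-fold) and Aen (2.12-fold). The call held with an estimated correlation (camera adjusted p = 4.57e-07; adjusted p = 0.013 with an estimated correlation). Cdkn1a rose 1.77-fold (adjusted p = 0.0013), while Trp53 was 890.2 ± 27.02 against 832 ± 59.7 (adjusted p = 0.373) and Mdm2 1273 ± 164 against 1111 ± 73.99 (adjusted p = 0.236). DNA replication genes rose in 15 of 43 cases (27 adjusted over the list alone), as in the helicase subunits Mcm4 (1.51-fold, adjusted p = 0.00781) and Mcm2 (1.96-fold, adjusted p = 0.00976). Integrated stress response genes rose in 9 of 27 (13 adjusted over the list alone), as in Sesn2 (1.53-fold, adjusted p = 0.00206) and Phgdh (1.55-fold). Immediate early genes rose in 11 of 22 (14 adjusted over the list alone), as in Egr2 (1.70-fold, adjusted p = 0.000383) and Zfp36 (1.44-fold). Epidermal lipid barrier genes rose in 9 of 25 (11 adjusted over the list alone), as in Smpd1 (1.52-fold, adjusted p = 0.000813) and the proteases Klk5 (1.77-fold) and Klk7 (1.85-fold). None fell in these 4 lists, which had adjusted p = 1.90e-10, 1.08e-06, 2.02e-05 and 4.57e-07 by camera (adjusted p = 0.387, 0.324, 0.324 and 0.332 with an estimated correlation). Skeletal muscle genes fell in 2 of 20 cases, Pvalb (1.82-fold) and Neb (1.34-fold) (5 adjusted over the list alone; camera adjusted p = 0.0101, and adjusted p = 0.588 with an estimated correlation). That list lost its call without P95H replicate 2 (adjusted p = 0.0642) or 4 (adjusted p = 0.0771); on the deposited values its median of -0.22 became 0.39 and Neb stood at 0.19.

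The largest rises of single genes at 28 days included the chitinase-like Chil4 (51.6-fold, adjusted p = 0.00076), the antisense transcript RP23-392I13.15 (36.3-fold, adjusted p = 6.49e-06) and Sprr2a2 (19.1-fold). The largest falls included Tgm7 (9.87-fold, adjusted p = 0.000881), the alcohol dehydrogenases Adh6b (9.44-fold) and Adh6a (5.97-fold), Ankrd1 (6.56-fold), Mrgprb11-ps (6.14-fold), Mrgprb3 (5.63-fold), Xirp1 (4.08-fold) and Gabrp (3.83-fold). In all, 2226 of 18311 genes passed limma (4 P95H against 3 control mice), 1227 higher and 999 lower, and 5244 genes did not overlap between the groups (28.6%; chance gives 5.71%). The count was 1130, 1290 and 699 without control replicates 1, 2 and 4, 1233 without P95H replicate 2. It was 4763 with array weights, 1436 with only these 2 groups in the fit and 3980 with controls of both days pooled. Of the 53 passing genes taken by the naming rule, 39 kept the call whichever library was left out. The deposited values gave 614 higher and 14 lower, with the median of all genes at 0.59.

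Of the genes raised in P95H skin, 388 were raised at both days (48.6 expected by chance across genes), and 305 were lowered at both (29.6 expected); the 2 comparisons share no library but come from 1 fit. Tested directly, the P95H effect at 28 days exceeded that at 12 days for 2 genes: Apol7a (5.34-fold, adjusted p = 0.00528) and RP23-392I13.15 (15.9-fold, adjusted p = 0.0486). In 28-day skin Apol7a stood at 291 ± 49.7 with P95H and at 49.3 ± 8.74 in controls. Interferon response genes differed as a list, with a median log2 difference of 0.65 and 6 of 34 higher adjusted over the list alone. Sebaceous gland genes had a median of -0.58, with 9 of 24 lower adjusted over the list alone. The difference in effect was 2.61 for Cxcl10 (adjusted p = 0.279) and -1.05 for Elovl3 (adjusted p = 0.279). The hair shaft and inner root sheath list had a median of 2.57 and no gene past the threshold over the list alone. The lists had adjusted p = 1.32e-10, 5.50e-08 and 3.73e-08 by camera (adjusted p = 0.608, 0.544 and 0.627 with an estimated correlation). None of the 12 genes always named passed (smallest adjusted p = 0.611). On the deposited values 71 genes passed (70 higher and 1 lower), the median of all genes was 0.71 and the sebaceous list had a median of 0.14. With controls of both days pooled the hair list had -1.46 and 7 genes passed, and array weights gave 30. Leaving out either P95H library at 12 days gave 7 genes and leaving out 28-day P95H replicate 1 gave 5; 1 gene was left without any 1 of the 12-day controls, without 28-day control replicate 4 and without 28-day P95H replicate 2, 3 or 4, and also with a pseudocount of 0.5, no filter or a mean of at least 50.

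Control skin at 28 days against 12 days gave the background of that comparison. The cytochrome Cyp2e1 (6.31-fold, adjusted p = 0.0487) rose, to 708 ± 114 (n = 3) from 125 ± 67.98 (n = 5), as the 1 gene past the threshold by limma. Hair shaft and inner root sheath genes had a median log2 change of -4.01, and 35 of 42 fell adjusted over the list alone; Krt71 was 19.7 ± 9.81 against 3405 ± 4307 steps (adjusted p = 0.172). Adjusted over the list alone 3 of 24 sebaceous gland genes rose and 3 of 20 skeletal muscle genes fell, with medians of 0.40 and -0.26; Scd1 was 50449 ± 9023 against 36005 ± 6674 and Myh4 6592 ± 9196 against 36328 ± 4711. The 3 lists had adjusted p = 1.24e-27, 7.61e-07 and 8.66e-06 by camera (adjusted p = 0.477 for each with an estimated correlation). None of the 12 genes always named passed (smallest adjusted p = 0.289). The count of 1 (with 2144 genes at an unadjusted p under 0.05) became 2 without 12-day replicate 1, 56 without 12-day replicate 3, 3 without 28-day replicate 1 and 0 without 12-day replicates 2, 4 or 5 or 28-day replicates 2 or 4. Array weights gave 626, a pseudocount of 5 gave 2, a mean of at least 50 gave 3, TMM gave 3 and no filter gave 0. The deposited values gave 2 higher and 452 lower, with the median of all genes at -0.82 and that of the sebaceous list at -0.43.

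In sorted reporter-positive cells at 10 days the comparison asks what deletion changes in the recombined cells themselves. Besides Srsf2, the transcript Gm43430 fell, 4.14-fold (adjusted p = 0.0459). Dnah17 rose 17.5-fold, from 26.5 ± 1.502 to 493 ± 145 normalised counts, titin 13.6-fold (Ttn, 761 ± 216 against 53.8 ± 6.93) and the FGF-binding protein gene Fgfbp3 6.19-fold (2827 ± 579 against 459 ± 119.8; adjusted p = 0.0164, 0.0164 and 0.0459). 4931403M11Rik was listed at 0 in all 3 controls and at 211 ± 104 in knockout cells, and 4930428N03Rik at 0.225 ± 0.39 and 183 ± 64.9 (adjusted p = 0.0164 for both). These 7 genes, 5 higher and 2 lower, were all that passed limma of 17744 (n = 3 each; 3051 at an unadjusted p under 0.05), and 5079 genes did not overlap (28.6%; chance gives 10%). The Srsf2 gene is overlapped on the other strand by Mettl23 and Mfsd11, whose log2 changes were -0.043 and -0.51 (adjusted p = 0.935 and 0.325).

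No gene of the 3 lists that passed camera in sorted knockout cells passed alone. DNA replication genes had a median log2 change of 0.61 over 43 genes, as in Mcm7 (5811 ± 1164 against 3011 ± 189, adjusted p = 0.143). Immediate early genes, which respond within minutes to signals and to handling, had a median of -0.92 over 22 genes (9 fell adjusted over the list alone), as in Atf3 (26668 ± 12308 against 85390.1 ± 18334, adjusted p = 0.141) and Egr3 (2591 ± 489 against 5510.1 ± 346, adjusted p = 0.12). Cytosolic ribosomal protein genes had a median of -0.23 over 84, as in Rpl22l1 (2062 ± 163 against 3484 ± 147, adjusted p = 0.145). The lists had adjusted p = 1.54e-06, 7.05e-06 and 0.0363 by camera (adjusted p = 0.86 for each with an estimated correlation). The ribosomal list lost its call without control replicate 2 or 3 (adjusted p = 0.0587 and 0.257), without knockout replicate 1 (0.167) and with array weights (0.291). None of the 12 genes always named passed; Mdm2 was 6358 ± 1147 against 15834 ± 2361, Cdkn1a 25653 ± 7068 against 40636 ± 4914 and Krt6a 72016 ± 91432 against 3870.4 ± 1677 (adjusted p = 0.112, 0.233 and 0.16).

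Sorted knockout replicate 2 stood apart: a single gene, Gm26917, took 52.2% of its counts, against 9.13 to 10.4% in the other 5 libraries. Without it 407 genes passed, 183 higher and 224 lower, all 7 genes above among them. The rises then included Rrh (36.6-fold, adjusted p = 0.00417), Tmem236 (49.8-fold, adjusted p = 0.0219), Spink12 (78.7-fold, adjusted p = 0.0262), the wound keratin Krt6b (69.3-fold, adjusted p = 0.05) and the neuronal tubulin Tubb3 (31.9-fold, adjusted p = 0.0467). St6galnac2 (13.5-fold, adjusted p = 0.0177), the hyaluronan synthase Has1 (7.49-fold, adjusted p = 0.0208) and Mdm2 (2.60-fold, adjusted p = 0.0354) fell. That set was chosen after the data were seen. With all 3 libraries these 8 genes did not pass: the log2 changes were 4.35, 4.79, 3.97, 4.74, 4.27, -3.29, -2.69 and -1.32 in that order (adjusted p = 0.0738 to 0.328). Without any other library, and at equal totals, no gene passed limma, so the call of Srsf2 ended there as well. Its log2 change was then -2.89 to -2.42 over the left-out libraries, and -3.06 at equal totals, where the median of all genes was -0.38. On recovered reads edgeR called 3 genes (Srsf2 at -2.66, adjusted p = 0.0555) and DESeq2 1256, 690 higher and 566 lower; array weights gave 4079.

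Whole skin and sorted cells at 10 days of deletion, which share no library, had 3 raised genes in common, 4930428N03Rik, 4931403M11Rik and Dnah17 (0.675 expected by chance, exact hypergeometric p = 0.0199 across genes), and 1 lowered gene, Gm43430 (0.211 expected, p = 0.2). Of the 7 genes called in sorted cells 5 had the same sign in whole skin (71.4%), and Ttn and Srsf2 had the opposite sign. The 4 shared genes became 113 without sorted knockout replicate 2 and 0 without any other sorted library or at equal totals, 2 with edgeR in sorted cells, 343 with DESeq2 and 1050 with array weights.

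In sorted cells after DMBA/TPA no gene passed limma between heterozygous P95H and control mice (n = 3 each; 2376 of 14914 at an unadjusted p under 0.05, smallest adjusted p = 0.0586). Of the gene lists 19 passed camera, and 9 are described, with members given as values. Replication-dependent histones had a median log2 change of 0.33 (14 of 61 rose adjusted over the list alone), as in Hist1h2bc (1345 ± 172 against 916 ± 100.4, adjusted p = 0.115). Mitosis genes had 0.19 over 59, as in Espl1 (372 ± 36.5 against 269 ± 16.1, adjusted p = 0.146), and DNA replication genes 0.18 over 43, as in Mcm5 (654 ± 34.6 against 494 ± 78.97, adjusted p = 0.191). Immediate early genes had a median of -0.32 (10 of 22 fell adjusted over the list alone), as in Fosb (9186 ± 990.2 against 16375 ± 1614, adjusted p = 0.0936) and Klf4 (6234 ± 652 against 9682 ± 2227, adjusted p = 0.167). Integrated stress response genes had -0.31 (5 of 27 fell), as in Atf4 (3961 ± 405 against 5705 ± 858, adjusted p = 0.137). Cornified layer genes had -1.17 (10 of 25 fell), as in Cdsn (207 ± 59.9 against 526 ± 201, adjusted p = 0.107). Epidermal lipid barrier genes had -0.24 (4 of 25 fell), as in Spink5 (718 ± 74.6 against 1254 ± 202, adjusted p = 0.1). These 3 counts are adjusted over the list alone. The 7 lists had adjusted p = 7.00e-12, 5.17e-07, 0.000729, 1.06e-06, 2.15e-05, 7.22e-05 and 0.000867 by camera (adjusted p = 0.647, 0.688, 0.688, 0.647, 0.647, 0.647 and 0.647 with an estimated correlation). The cornified list lost its call over genes with a mean of at least 50 (adjusted p = 0.0556) and the replication list without control replicate 1 (adjusted p = 0.104). None of the 12 genes always named passed; Cdkn1a was 3022 ± 366 against 3912 ± 344 (adjusted p = 0.189). The groups did not overlap for 3213 genes (21.5%; chance gives 10%). Limma called 114 genes without P95H replicate 1, 4 without P95H replicate 3, 2 without control replicate 3, 73 with no filter, 1 at equal totals and 1 with array weights; edgeR called 1 and DESeq2 350, 110 higher and 240 lower.

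Markers of other cell types also differed in these sorted cells. Fibroblast markers had a median log2 change of 0.38 (4 of 13 rose adjusted over the list alone), and macrophage and dendritic cell markers -1.03 over 7, with scores of 4.91, 5.14 and 7.31 in P95H and 6.33, 6.76 and 7.05 in control libraries. The lists had adjusted p = 0.00993 and 0.0389 by camera (adjusted p = 0.647 and 0.688 with an estimated correlation). Both lost their calls without control replicate 3 (adjusted p = 0.174 and 0.169). The macrophage list also lost it without P95H replicate 1 or 2 (0.209 and 0.138), over genes with a mean of at least 50 (0.154), with array weights (0.101) and with DESeq2 (0.331). Differences in the make-up of the sorted cells were not set apart from differences within them. These 2 lists were chosen after their values were seen.

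**Figure D3:**
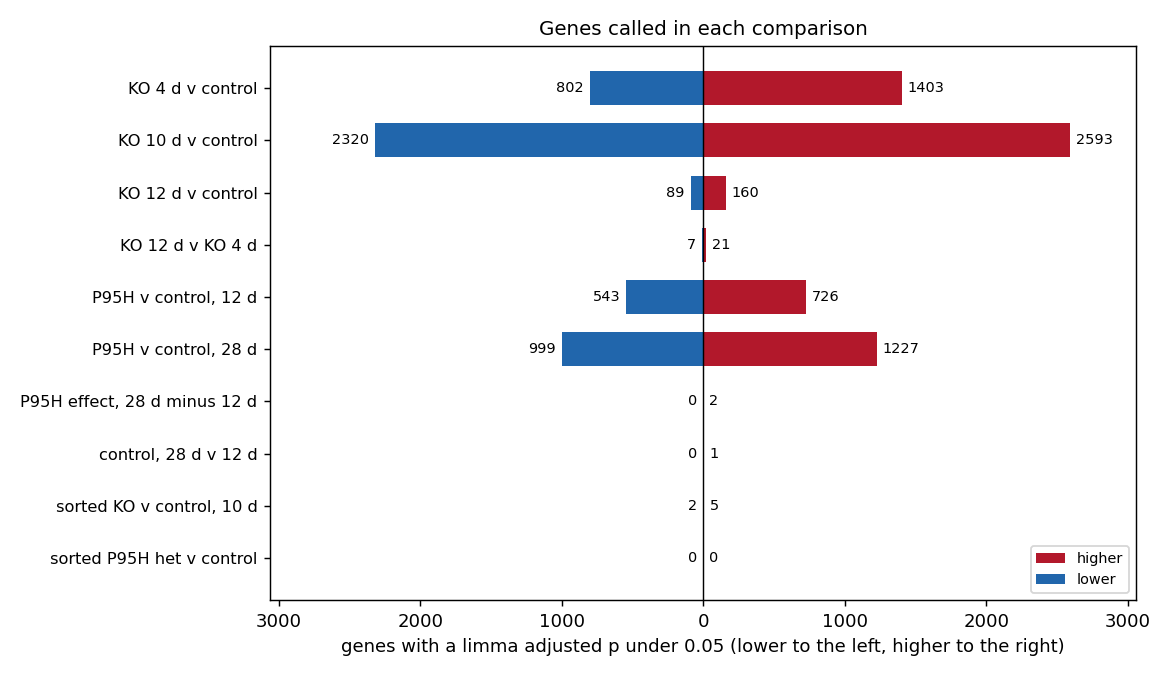
Number of genes past the limma threshold in each comparison, with lower genes as bars to the left of 0 and higher genes to the right; the numbers at the bars are the counts. The count was highest at 10 days of deletion in whole skin.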

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

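The tests of hair cycle stage and of a genomic segment linked to Srsf2 were chosen only after the result was seen. So was the test of Cre or tamoxifen for the 2 RNAs 4930428N03Rik and 4931403M11Rik. The pattern tested for Dnah17 was narrowed to that gene after its test, and the sorted cells were brought in for it after their values were seen.

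Some samples lay far from the others of their group. Srsf2 was 2597 steps in P95H replicate 1 at 28 days, against 3355 to 3450 in the other 3 libraries. The hair shaft and inner root sheath score of the same library was 4.16, against 3.71 to 3.76, and its fibroblast score was 11.9, against 11.4 to 11.5. This library was also the shallowest of its set by its step (spacing of 2.35), so depth and animal cannot be told apart. In 12-day control replicate 5, Krt5 was 37440 steps (others 43726 to 45935) and Krt1 12469 (others 18920 to 21496). These are 5 of 60 such tests, and chance gives about 1 in 20, or 3 here.

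Knockout skin differed between 12 and 4 days for 28 genes by a direct test; with no control treated for 4 days used here, a difference in the effect of deletion itself was not tested. In log2, Stfa1 4.43, Dnah17 2.33, Ccl20 2.29, Rrh 1.72, Csta1 1.17, Tmem56 1.12, Defb1 1.04 and Cdkn2b 0.83 were higher at 12 days. Cd5l -3.20, Col6a6 -2.20, Lyve1 -1.77, Ms4a8a -1.32, Ccl6 -1.32, Fcna -1.30 and Adamts15 -1.001 were lower. Among these falls, Cd5l, Lyve1 and Fcna are genes of tissue macrophages or lymphatic vessels. That grouping was made after the genes were seen and was not tested. The P95H effect differed between 28 and 12 days for 2 genes, RP23-392I13.15 3.99 and Apol7a 2.42. Without knockout replicates 1, 2 or 3 at 4 days 3, 11 and 7 genes differed between days, and 4 and 8 without replicates 2 or 3 at 12 days. For the P95H difference 7 genes passed without either 12-day P95H replicate, 5 without 28-day P95H replicate 1, and 1 without 28-day P95H replicates 2, 3 or 4, 28-day control 4 or any 12-day control.

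Hair shaft and inner root sheath genes rose at 10 days of deletion, with a median log2 change of 6.31. In sorted cells of the same day the list median was -0.49 over 22 members, so no rise was seen in the cells that were sorted. Only these 22 of 42 genes reached the level tested there, and the cells came from other mice. Whether that fraction held cells that form hair is not known, so a rise within recombined cells of the sampled skin stays open. The hair cycle stage of the sampled skin may explain the rise: the score ranged over 4.81 among controls of the knockout set and over 5.03 among 12-day controls of the P95H set, where nothing was deleted. That range is near the change itself but below it, all 3 libraries at 10 days were high, and no label gives the hair cycle stage, so stage and deletion cannot be told apart for these libraries.

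Dnah17, 4930428N03Rik, 4931403M11Rik and Ttn were higher in knockout cells. Dnah17 lies 1.17 Mb from Srsf2, and a linked segment alone was predicted to give like levels at both times. Its level differed by 2.33 (log2) between knockout skin at 12 and 4 days. No control treated for 4 days was used, so a change with treatment is not set apart and a linked segment stays open. In P95H skin the rise of Dnah17 did not differ between 28 and 12 days (log2 -0.011, adjusted p = 0.996 by limma). Active Cre could contribute to Dnah17, which was 1.42 higher in Cre-positive P95H than in Cre-negative skin at 12 days, both given tamoxifen (95% interval 0.85 to 1.999; at 28 days 0.89 to 1.94), and there Cre and the mutation cannot be told apart because each P95H library is Cre positive. Sorted P95H cells after DMBA/TPA had Dnah17 at 5.58 ± 3.80 against 4.66 ± 3.52, below the level tested. In sorted reporter-positive cells Dnah17 was 26.5 ± 1.502 in controls against 493 ± 145 in knockouts, which argues against Cre as the whole cause if the reporter marks active Cre in both, but the labels do not give the Cre status of those mice. Cre is argued against for the 2 RNAs, whose highest level in 6 P95H skin libraries was 2% of the lowest knockout library at 12 days. Muscle cells in the sorted fraction are argued against for Ttn by 6 abundant muscle transcripts. Their median was 2.49% of the level that whole-skin ratios to Ttn would give, with Mylpf the exception at 583%. Outside that set the muscle genes Myl1 and Mybph stood at log2 4.98 and 4.36 (adjusted p = 0.0711 and 0.142, and both passed without replicate 2). The skeletal muscle list, with Ttn among its 8 measured members, had a median of 0.75 in sorted knockout cells. Fry gave adjusted p = 0.0133 for that list and camera adjusted p = 0.0596. These values go the other way, so muscle cells are not excluded.

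Sorted knockout cells gave 7 genes at 10 days, where whole skin gave 4913. A candidate explanation is knockout replicate 2, where Gm26917 took 52.2% of the counts: without it 407 genes passed. Without any other single library of that comparison none passed by limma, so the low count is not a measure of the size of the response. No biological explanation was tested.

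Other splits of the same samples were compared with the real one. In P95H skin at 28 days the real split alone, 1 of 35, gave 2226 genes. That share is under 0.05 and is the smallest the test can give. It was not adjusted over the comparisons, so chance is less likely there but not excluded. The highest other split, P95H replicate 3 and the 3 controls against the rest, gave 1004. Between control days 7 of 56 splits gave at least 1 gene, so chance cannot be excluded, and a split that sets 12-day controls 1, 2 and 5 apart gave 68, which points to a structure among the control samples. With 10 splits each, the comparisons of 3 against 3 libraries have too few for a share under 0.05, and splits were not counted for P95H at 12 days (2 P95H libraries) or for the difference of the P95H effects. With 3 against 3, 1 split, the real one, gave the most genes at 4 days (2205, highest other 1), 10 days (4913, 0), 12 days (249, 64), 12 against 4 days (28, 1) and in sorted knockout cells (7, 0). After DMBA/TPA 10 of 10 gave at least the real 0 (highest other 1).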

How the results depend on the processing

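The plan named the normalised counts, and steps replaced them in whole skin after the values of the tables were seen. The deposited values of whole skin, the planned unit, thereby became an alternative. The other alternatives were planned. The main values are 2205, 4913, 249 and 28 genes (4, 10 and 12 days of deletion, and 12 against 4 days), 1269 and 2226 (P95H at 12 and 28 days), 2 (difference of the P95H effects), 1 (control days), 7 (sorted knockout cells) and 0 (sorted cells after DMBA/TPA). Counts not given below stayed within 1.5 times of these.

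Filters and pseudocounts moved short lists of genes most. For 12 against 4 days, a pseudocount of 5 gave 60 genes, no filter 53 and a mean of at least 50 gave 15. That mean gave 153 at 12 days of deletion. For the difference of the P95H effects a pseudocount of 0.5, no filter and a mean of at least 50 gave 1 each. Between control days a pseudocount of 5 gave 2, no filter 0, and a mean of at least 50 and TMM 3 each. After DMBA/TPA no filter gave 73. In sorted knockout cells 6 lists passed in place of 3 with a pseudocount of 5 or a mean of at least 50. The cause was not tested.

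Equal totals gave 8018 genes at 10 days of deletion, 61 for 12 against 4 days, 0 in sorted knockout cells and 1 after DMBA/TPA. Srsf2 reversed at 10 days (-0.17), in P95H skin at 28 days (-0.039) and after DMBA/TPA (0.016), Srsf6 reversed at 10 days (-0.027), and Srsf2 in sorted knockout cells (-3.06) no longer passed. There 8 lists passed, and 0 genes were shared with whole skin. On the deposited values 743 genes passed at 4 days, 110 at 12 days, 200 and 628 in P95H skin at 12 and 28 days, 71 for the difference of those effects and 454 between control days. There Srsf2 reversed for 12 against 4 days (0.038), P95H at 12 days (-0.037) and the difference of effects (0.66), and Neb reversed in P95H skin at 28 days (0.19). Both settings shift whole libraries by construction, and beyond that the cause was not tested.

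Array weights gave 947 genes at 12 days, 975 for 12 against 4 days, 2329 and 4763 in P95H skin at 12 and 28 days, 30 for the difference, 626 between control days, 4079 in sorted knockout cells (7 lists, 1050 genes shared with whole skin) and 1 after DMBA/TPA. With only the groups compared in the fit, 764 passed at 4 days, 111 at 12 days and 1436 in P95H skin at 28 days; fewer samples then estimate the spread. Only the 12-day controls left 44 at 12 days. Pooled controls gave 3980 in P95H skin at 28 days, with Srsf2 reversed (-0.068), and 7 for the difference of effects, where the hair shaft and inner root sheath list reversed (-1.46). Apart from the smaller fits the cause was not tested.

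Replicate numbers were read as labels that do not pair the samples. In both sorted sets, deviations from the group mean correlated best between libraries of the same number in 3 of 3 pairs. Same-number r was 0.058 to 0.19 in the knockout set and 0.056 to 0.15 after DMBA/TPA (others -0.159 to -0.005 and -0.141 to 0.024). Pairing therefore stays open for the sorted cells. With the replicate block 16 genes passed for 12 against 4 days, 786 in P95H skin at 12 days and 1 for the difference of effects. It gave 0 between control days, 0 in sorted knockout cells (6 lists, 0 genes shared with whole skin) and 113 after DMBA/TPA. Srsf2 was then -2.71 in sorted knockout cells (adjusted p = 0.0572) and -0.032 in P95H skin at 28 days, the reverse sign. The block uses up degrees of freedom, so a lost call there is not a smaller effect.

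Other tools were run on the reads of the sorted tables only; edgeR and DESeq2 were not run on whole skin, where reads could not be recovered. In sorted knockout cells edgeR gave 3 genes (7 lists, 2 shared genes; Srsf2 -2.66, adjusted p = 0.0555) and DESeq2 1256 (5 lists, 343 shared genes), and after DMBA/TPA 1 and 350. Camera with an estimated correlation left 1 list (p53 targets) in P95H skin at each day and 0 in each of the other 8 comparisons, in place of 3 to 20. Fry gave 5 lists at 4 days, 3 at 12 days and 9 in P95H skin at 28 days, and 0 for 12 against 4 days, the difference of effects, control days and after DMBA/TPA. The cause was not tested.

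Leaving out each library in turn gave 295 to 2585 genes at 4 days, 1424 to 4869 at 10 days, 43 to 144 at 12 days, 3 to 26 for 12 against 4 days, 323 to 1438 and 699 to 2442 in P95H skin at 12 and 28 days, 1 to 7 for the difference, 0 to 56 between control days, 0 to 407 in sorted knockout cells (2 to 11 lists, 0 to 113 genes shared with whole skin) and 0 to 114 after DMBA/TPA. Where an arm held 1 library, it was assumed to vary like the other groups. Srsf2 ranged from -2.89 to -2.42 in sorted knockout cells, and from -0.034 to 0.10 in P95H skin at 28 days and -0.12 to 0.038 for the difference of effects, where no call was made and the sign reversed. For named genes 1493 of 1946 values kept sign and side of the threshold over the left-out libraries, 213 of 296 on the deposited values, 279 of 301 at equal totals and 300 of 301 with TMM; of described lists, 486 of 500, 61 of 63, 74 of 75 and 75 of 75 did. Array weights kept 298 of 301 gene values and the number of tdTomato alleles as a covariate 166 of 179; values not kept were in the same direction and lost the threshold, apart from the reversals given above.

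Depth limits what low genes can show; its lowest value was in a library of P95H skin, at 7.37 M reads, and the rescaled steps of whole skin hide counting error.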

Other observations

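The gene length test was set before its result was seen; the lists described here and the shared genes of knockout and P95H skin were chosen only after the results were seen.

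Further groups of genes moved in skin. At 4 days of deletion 8 of 33 genes of skin tumour progression rose and none fell over all genes (9 and 2 adjusted over the list alone), among them the protease Plau (2.38-fold) and fibronectin (Fn1, 2.68-fold), which fibroblasts also express. Camera gave adjusted p = 0.0302 (adjusted p = 0.595 with an estimated correlation; 0.106 over genes with a mean of at least 50, 0.0769 without control replicate 2). At 10 days 10 of 27 integrated stress response genes rose and none fell over all genes (12 and 1 adjusted over the list alone), with the glutathione-degrading enzyme Chac1 (11.7-fold, adjusted p = 0.0107), the cystine transporter Slc7a11 (11.6-fold, adjusted p = 0.00754) and Sesn2 (1.67-fold) (camera adjusted p = 0.0057; adjusted p = 0.605 with an estimated correlation). In P95H skin at 12 days 4 of 23 fibroblast markers rose (9 adjusted over the list alone), including lumican (Lum, 1.82-fold), and 4 of 24 macrophage and dendritic cell markers (11 rose and 1 fell adjusted over the list alone), including Cd14 (2.86-fold, adjusted p = 0.000569). Lum did not pass without P95H replicate 2 (adjusted p = 0.0718) or with pooled controls (0.0842), and on the deposited values neither Lum nor Cd14 (Cd14 adjusted p = 0.176) did. Both lists passed camera (adjusted p = 4.85e-07 and 2.48e-06; adjusted p = 0.342 for each with an estimated correlation).

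Knockout and P95H skin, which share no library, had genes in common, given here with the number expected for unrelated lists. At 10 days of deletion and 28 days of P95H 486 (expected 154) rose in both and 423 (expected 124) fell in both. At 12 days of each, 50 (expected 4.85) rose in both and 21 (expected 2.46) fell. Serpinb3a and Stfa1 were raised at 12 days in both sets. At 4 days of deletion and 28 days of P95H the numbers were 74 (expected 90.99) higher and 95 (expected 42.01) lower, while 30 genes raised and 67 genes lowered at 4 days went the opposite way in P95H skin. Genes move together, so these expectations are not tests with independent units, and the numbers were not recomputed under other settings.

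A hypothesis from the role of SRSF2 in transcription is that long genes lose expression on its deletion. Over 13669 protein-coding genes in sorted knockout cells, the quintile of longest genes (median 124 kb) changed by -0.43 (log2 median) relative to the quintile of shortest genes (median 4.40 kb). The difference was -0.29, -0.75 and -0.24 in the 3 knockout libraries, -0.27 without replicate 2, and -0.028 to 0.0071 when each control was set against the other 2. It was -0.21 in whole skin at 10 days and -0.052 in sorted heterozygous P95H cells. The values are those that a loss with gene length predicts; RNA quality, which may also depend on length, was not tested, so this remains a hypothesis.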
